A study of Glycine max with 18 samples.

How the data were processed

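Nuclei of soybean organs were isolated and sorted, and their RNA was made into 3′ libraries with a v2 droplet kit, per the labels' protocols. The trifoliate libraries carry barcodes of another list than the other libraries, so the kit named may not hold for all. The deposited values are raw UMI counts per gene and nucleus barcode, 1 matrix per library, made with Cell Ranger 6.1.2 per the file headers. The submitters' processing notes name Cell Ranger 6.1.1 and Seurat, with no version given for Seurat and no genome build. The deposited count matrices hold barcodes that the authors or their software kept as nuclei, and the smallest barcode totals are 500 to 503 UMIs. Each matrix lists the same 57147 features: 55897 GLYMA_ loci and 1250 noncoding features, of which 365 are rRNA. The files pair 108 GLYMA_ loci with a gene name (101 distinct names), and 0 of the feature IDs matched the reference table, so all other loci are given by ID alone. Loci that share reads with near-identical copies (glycinin and other globulin genes, RPS13, ubiquitin and rRNA copies, and nuclear loci with plastid gene names) are uncertain, since the sources used here do not say how reads that fit several loci were counted.

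Libraries were grouped by organ and stage as labelled. UMI counts were summed over all deposited barcodes of a library, because nuclei are not replicates. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 44314, and libraries were scaled by TMM. One quasi-likelihood model of group means (edgeR 4.0.16, limma 3.58.1, R 4.3.3) was fitted to all 18 libraries, with a common biological coefficient of variation of 0.4816. Comparisons were early cotyledon minus heart stage seed, mid-maturation minus early cotyledon seed, trifoliate minus true leaf, and each of 5 organs minus the mean of the other organs. In an organ comparison, stages or leaf types were first averaged on the log scale and organs weighted equally, so that a fold change can differ from a ratio of the mean CPM values. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. CPM values are UMIs over the library total multiplied by its TMM factor (0.696 to 1.23), per 1e6. Where a side had 0 UMIs, a bound was computed against a floor of 3 counts over the group, and with 1 to 3 UMIs a ratio with its exact 95% counting interval; these cover counting error only.

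The test, the groups, the thresholds, the lists by gene ID, the rule for named genes and the first set of other settings were chosen before the data were examined. Named genes were up to 12 higher and 12 lower per comparison with the largest fitted fold among called genes that carry a name in the files, with a mean of at least 20 CPM on the higher side and no overlap between the sides' libraries. To these were added at most 2 loci per direction with an ID alone, members of lists past the set test (up to 4 that passed, by level, and up to 2 that did not), and loci listed beforehand by ID. Those lists were seed globulins, seed protease inhibitors, embryo maturation regulators, floral organ identity, flowering time, sugar transport, lipoxygenase, circadian clock and pod dehiscence. Lists planned as patterns on gene descriptions could not be used, since the files hold no descriptions. In their place, 12 lists were made from the gene names in the files after the data had been seen. Lists of at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over all lists and comparisons; camera with an estimated correlation and limma's fry were the alternatives.

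For classes of nuclei, barcodes with at least 500 UMIs and 300 genes were kept (108475 nuclei). Scrublet's automatic thresholds, run per library with an expected rate of 0.06, called 0 doublets in several libraries, and 34.8% of nuclei in heart stage replicate 2. For clustering, the nuclei with the highest scores were therefore removed instead, at 0.8% per 1000 nuclei, a choice made after the data had been seen. Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 0.8 gave the groups (scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0), over 7 seed and over 5 leaf libraries. A group was named where at least 3 markers of a class were raised and found in at least 5% of its nuclei. Raised meant at least 2 times higher than in other nuclei of the same libraries. A group with at least 3 markers of both the embryo and the storage cotyledon class was left unnamed. So was a group of shallow nuclei with none of the class's markers among its leading genes. This scoring was set after the data had been seen. Clusters for loci listed beforehand were recomputed without those loci. Tests within endosperm-like, seed coat-like, embryo-like (mid-maturation minus early cotyledon seed) and mesophyll-like nuclei were planned and not run: the markers of 3 of these classes match no names in the files, and embryo-like nuclei numbered 6 in mid-maturation replicate 1, under the minimum of 50. After the data had been seen, early cotyledon minus heart stage seed was tested within embryo-like nuclei (28307 genes).

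The other settings chosen at that point were scaling by DESeq2's size factors within edgeR, no filter on low counts, DESeq2 1.42.0 in place of edgeR, a fit with the replicate number as a block, a fit of only the 2 groups compared, counts after the filter of nuclei with Scrublet's automatic calls removed, thinning of all libraries to the smallest (8014214 UMIs), each library left out in turn, Leiden resolution 0.4, and a minimum of 1000 UMIs per nucleus. Further settings were added after the data had been seen: removal of nuclei by Scrublet score, the 2-group fit with the block, counts without rRNA features and loci with plastid gene names, fits without the 3 trifoliate libraries, and counts without barcodes shared between seed libraries. Intervals for shares are exact binomial at 95%, and intervals for medians and correlations come from 1000 bootstrap draws over genes. The test was checked on simulated libraries with 200 genes changed by 2-, 4- or 8-fold: edgeR recovered 10% of 4-fold and 69.1% of 8-fold changes in mid-maturation minus early cotyledon seed (42489 genes), 35.4% and 81.7% in trifoliate minus true leaf (42542 genes), and 95.8% and 100% in seed minus other organs (42517 genes). False calls in these 3 simulations numbered 1, 9 and 9 with edgeR, and 46, 47 and 38 with DESeq2. In early cotyledon minus heart stage seed they were 1 and 51. Every simulated library took its spread from the trend over all 18 libraries and its levels from each gene's mean over them. Only genes with a mean of at least 5 CPM were changed. The recovered shares therefore hold for that spread, not for the spread of the groups compared. Other computing used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. All deposited barcodes entered the whole-library sums, and 0 matrix columns were left out.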

Results

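RNA in sorted nuclei of soybean (Glycine max, cultivar Williams 82) was counted with droplet libraries, as unique molecular identifiers (UMIs) per gene and nucleus barcode. The series holds 18 libraries in 8 groups: heart stage seed (3 libraries), early cotyledon seed (2), mid-maturation seed (2), green pod (2), flower bud (2), shoot apical meristem (SAM, 2), true leaf (2) and trifoliate leaf (3). The matrices hold 109865 nuclei and 478683346 UMIs. Total UMIs were 52556290, 51397124 and 48246337 in heart stage replicates 1 to 3. They were 47738298 and 52012554 in early cotyledon replicates 1 and 2, and 36953323 and 31040030 in mid-maturation replicates 1 and 2. Green pod held 24687873 and 8014214 UMIs, flower bud 11026555 and 8802340, SAM 13884444 and 10914211, and true leaf 15718519 and 26803423. Trifoliate leaf held 21150110, 8880480 and 8857221 UMIs in replicates 1 to 3. The median nucleus held 752 UMIs in the shallowest library (trifoliate leaf replicate 3) and 4257 in the deepest (heart stage replicate 3). The labels do not say whether replicates came from separate plants, so every p-value below measures only the spread between these samples. Levels are counts per 1e6 UMIs of the library's TMM-scaled size (CPM; factors 0.696 to 1.23), given as mean ± SD over libraries, and fold changes are log2 values ± standard error.

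edgeR called no gene between the youngest seed stages, 246 between the leaf types and 2749 to 16833 between organs. Its quasi-likelihood test with Benjamini-Hochberg adjustment was run on 44314 genes, and a gene was called at an adjusted p under 0.05 and a fold of at least 2.

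**Figure D1:**
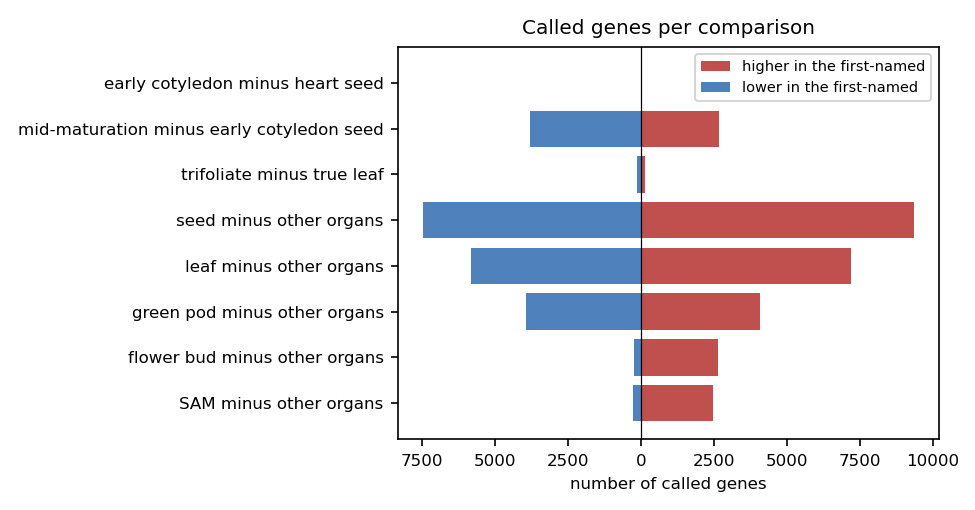
Number of called genes (x axis, linear from 0) in each of the 8 comparisons (y axis), with genes higher in the first-named side to the right and lower ones to the left. Seed against the other organs has the longest bars, 9361 higher and 7472 lower, and early cotyledon against heart stage seed has none.

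The first comparison asked what changes between heart stage and early cotyledon seed. No single gene passed edgeR's test between these stages. Transcripts of most storage proteins were scarce at both stages. GY1, a glycinin subunit, had 71 UMIs in early cotyledon seed and 0 in heart stage seed, which is at least 35.4-fold higher against a floor of 3 counts over the group, yet edgeR's adjusted p was 1. It stood at 0.0344 CPM in early cotyledon replicate 1 and 1.11 in replicate 2, and without replicate 2 its count was under that floor. The globulin locus GLYMA_10G246300, listed beforehand under seed globulins, stood at 31.7 ± 40.7 CPM (n = 2) in early cotyledon seed and 2.34 ± 2.66 (n = 3) in heart stage seed.

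Gene by gene, edgeR called 0 of 44314 genes, with 398 higher and 70 lower at an unadjusted p under 0.05, and DESeq2 called 6 (5 higher, 1 lower). As a set, the 9 tested seed globulins ranked higher in early cotyledon seed than other genes (limma's camera with a preset correlation, adjusted p = 1.66e-08; adjusted p = 0.256 with an estimated correlation). None of the 9 was called by edgeR over all genes, and 3 were higher when adjusted over the list alone. The 8 seed storage and maturation genes named in the files ranked higher too (camera adjusted p = 6.27e-10; adjusted p = 0.236 with an estimated correlation). Of these 8, 0 were called and 2 were higher when adjusted over the list alone. Their member SLE1 stood at 19.5 ± 8.27 CPM (n = 2) in early cotyledon and 5.41 ± 0.758 (n = 3) in heart stage seed. The 7 embryo maturation regulators also ranked higher (camera adjusted p = 0.0205; adjusted p = 0.796 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. Among them, GLYMA_18G176100, listed beforehand under embryo maturation regulators, stood at 155 ± 124 CPM (n = 2) in early cotyledon and 90.6 ± 67.6 (n = 3) in heart stage seed. Among these 5 libraries it was highest in early cotyledon replicate 2 (243.2) and heart stage replicate 2 (165.5), where embryo-like nuclei held 26.5% and 22.7% against 4.58% to 7.77% in the others. The globulin locus GLYMA_10G246300 was highest in the same libraries (60.4 and 5.42). Embryo-like groups were named from embryo maturation regulators, so for GLYMA_18G176100 the match of level and share is partly built in. The 14 housekeeping genes named in the files ranked lower (camera adjusted p = 0.00331; adjusted p = 0.723 with an estimated correlation), with 0 called. The polyubiquitin gene SUBI-1 (GLYMA_20G141600) stood at 389 ± 118 CPM (n = 2) in early cotyledon and 526 ± 86.6 (n = 3) in heart stage seed. Of the 3 lipoxygenase loci listed beforehand, 0 were called and 2 were higher when adjusted over the list alone. Across genes, which are not independent replicates, early cotyledon replicate 1 correlated at 0.972 with heart stage replicate 1 and at 0.931 with early cotyledon replicate 2. In simulated libraries of this comparison the same test recovered 2.94% of genes changed by 2-fold, 23.8% by 4-fold and 78.3% by 8-fold (42545 genes). Most changes of 2-fold or 4-fold would thus be missed at the simulated spread. That spread was a trend over all 18 libraries, not that of the heart stage and early cotyledon libraries alone.

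Mid-maturation against early cotyledon seed asked what changes as the seed fills. Of the 9 tested seed globulins 7 rose, as did all 3 lipoxygenase loci listed beforehand and 7 of the 8 storage and maturation genes named in the files. GY1 rose to 9564 ± 6250 CPM (n = 2) from 0.573 ± 0.762 (n = 2), and BG, the basic 7S globulin, to 999.6 ± 1050 from 0.287 ± 0.164. GMPM1, a seed maturation protein, rose to 1408 ± 897 CPM from 1.44 ± 1.04. PRP1 and PRP3, proline-rich cell wall proteins, fell: PRP1 to 2.86 ± 1.55 CPM from 188.8 ± 111 and PRP3 to 4.06 ± 1.88 from 88.7 ± 22.8 (n = 2 in each group).

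**Figure D2:**
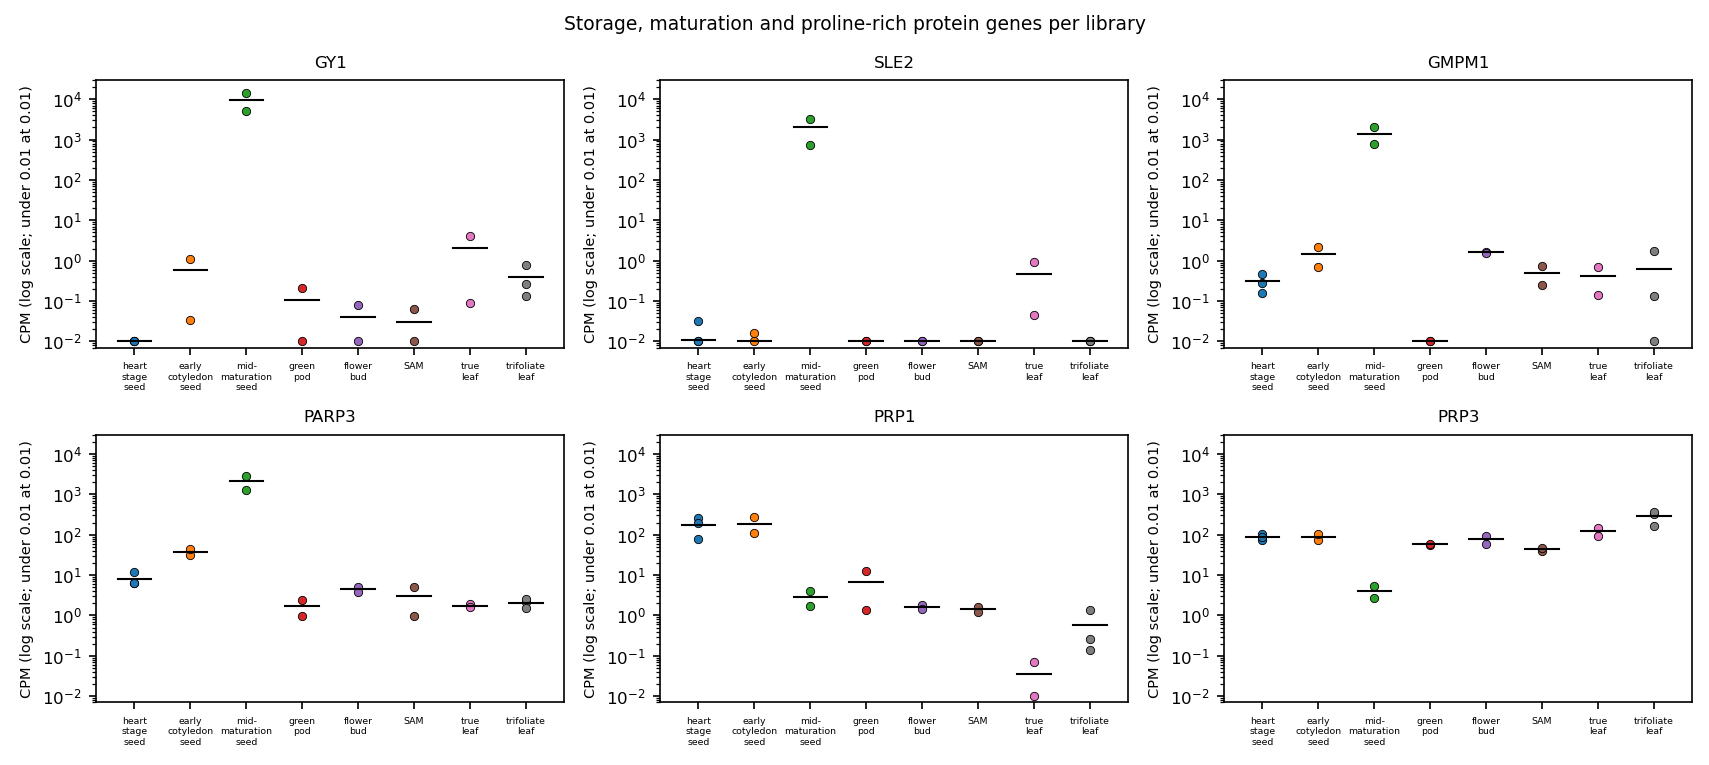
Levels of 6 genes in each library (y axis, CPM on a log scale, values under 0.01 drawn at 0.01) by group (x axis); dots are libraries and horizontal lines are group means. Both mid-maturation libraries lie above every other library for GY1, SLE2, GMPM1 and PARP3, and their mean for PRP3 is 4.06 against 88.7 in early cotyledon seed.

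edgeR called 6484 of 44314 genes, 2693 higher and 3791 lower in mid-maturation seed. Among the 9 tested seed globulins, 7 were higher (7 also when adjusted over the list alone), and camera gave an adjusted p = 1.18e-14 (adjusted p = 0.170 with an estimated correlation). GY1 changed by 14.01 ± 2.16 (edgeR adjusted p = 0.00319) and was higher in both mid-maturation libraries. GY3, another glycinin subunit, had 18714 UMIs against 3 (ratio 13580, counting interval 4646 to 65856; edgeR adjusted p = 0.000462). The globulin loci GLYMA_13G123500, GLYMA_10G037100 and GLYMA_10G246300, listed beforehand under seed globulins, reached 750.1 ± 346, 4234 ± 1990 and 6224 ± 157 CPM (n = 2). GLYMA_20G148400 and GLYMA_20G148300, also listed beforehand, did not pass: they stood at 712.5 ± 290 against 12.7 ± 17.8 CPM and at 3.06 ± 1.21 against 0.145 ± 0.205 (edgeR adjusted p = 0.175 and 0.167, n = 2). Of the 8 storage and maturation genes named in the files, 7 were higher (8 when adjusted over the list alone), with a camera adjusted p = 1.43e-10 (adjusted p = 0.182 with an estimated correlation). They include SLE1, at 2093 ± 795 against 19.5 ± 8.27 CPM (6.75 ± 0.65, edgeR adjusted p = 0.00024), SLE2, with 97233 UMIs against 1 (ratio 211673, counting interval 37990 to 8360720), and the seed lectin LE1, at 1191 ± 18 against 12.9 ± 15. FAD2-1, an oleate desaturase, stood at 183.1 ± 50.7 against 7.06 ± 9.54 CPM and did not pass (edgeR adjusted p = 0.0954). All 3 lipoxygenase loci listed beforehand rose: GLYMA_13G347600 to 2366 ± 262 CPM, GLYMA_13G347500 to 4434 ± 1070 and GLYMA_15G026300 to 4539 ± 1600 (n = 2). GLYMA_08G341500, listed beforehand under seed protease inhibitors, rose to 5682 ± 381 CPM from 116.7 ± 135. PARP3, a poly(ADP-ribose) polymerase, rose to 2088 ± 1090 from 38.2 ± 10.1 CPM, and CYP93E1, of soyasaponin synthesis, to 494.7 ± 174 from 13.7 ± 7.44. Among lower genes were CYP73A11, a cinnamate 4-hydroxylase, at 24.03 ± 4.77 against 65.4 ± 0.970 CPM, and PPC16, a phosphoenolpyruvate carboxylase, at 11.5 ± 2.66 against 27.0 ± 2.45. The locus GLYMA_18G257200 had 0 UMIs against 5858 and was at least 897-fold lower, against a floor of 3 counts over the group. None of the 7 embryo maturation regulators was called over all genes, and 0 passed when adjusted over the list alone: GLYMA_18G176100 stood at 322.9 ± 18.4 CPM (n = 2) in mid-maturation seed and 155 ± 124 in early cotyledon seed. GLYMA_16G050500 had an edgeR adjusted p = 0.0387 with a change of -0.95, under the fold asked for. The count of calls was 9740 with DESeq2, 3029 with only the 2 groups in the fit, 2148 without mid-maturation replicate 2, 1555 without early cotyledon replicate 1 and 2981 without early cotyledon replicate 2. The calls of CYP93E1, CYP73A11 and GLYMA_08G341500 ended without any 1 of the 4 libraries (edgeR adjusted p up to 0.217, 0.166 and 0.225), those of LE1 and GLYMA_15G026300 without mid-maturation replicate 2 or either early cotyledon library (up to 0.161 and 0.146), those of GLYMA_10G246300 and PPC16 without mid-maturation replicate 2 or early cotyledon replicate 1 (up to 0.113 and 0.143), and that of GLYMA_13G347500 without early cotyledon replicate 1 (0.06).

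Nuclei of the 7 seed libraries were grouped by their transcripts, to ask which classes each stage holds. Groups named from globulin loci, called storage cotyledon-like, were found in mid-maturation seed alone. They held 15.4% of nuclei in mid-maturation replicate 1 (exact 95% binomial interval 14.6 to 16.2) and 37.8% in replicate 2 (36.6 to 39.1), a mean of 26.6% ± 15.9 (SD, n = 2). In the 5 younger libraries 0 nuclei fell in them, which allows shares of up to 0.0442% to 0.0542% at 3 nuclei of a library's total. Most globulin transcripts were near 0 in the younger libraries, so the absence of this class there follows largely from its markers. With coarser grouping (Leiden resolution 0.4) or a minimum of 1000 UMIs per nucleus the share in replicate 1 was 15.2% or 16.2%, but in replicate 2 it was 0.178% or 0.115%. Groups named from embryo maturation regulators, called embryo-like, held 4.58%, 22.7% and 7.77% of nuclei in heart stage replicates 1 to 3, and 7.39% and 26.5% in early cotyledon replicates 1 and 2. In mid-maturation seed they held 0.0735% (0.0270 to 0.160) in replicate 1 and 25.7% (24.5 to 26.8) in replicate 2, where the share was 0 with coarser grouping and 36.0% with a minimum of 1000 UMIs. A group that passed the marker rule for both classes was left unnamed. Shares of either class can therefore change with the naming of groups alone, which was not tested. The spread within a stage was as large as the differences between stage means (11.7% ± 9.68, 16.9% ± 13.5 and 12.9% ± 18.1 in order of stage), and 3 libraries against 2 make only 10 splits, too few for an exact test to reach p = 0.05, so none was run. Of 35 groups of seed nuclei, 5 were embryo-like, 2 storage cotyledon-like and 28 had no name, and 9 drew over 90% of their nuclei from 1 library. None of the 28 leaf groups could be named from the gene names in the files.

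Trifoliate leaf against true leaf asked how the leaf types differ. Of the 10 tested loci that carry plastid gene names, 5 were higher in trifoliate leaf. petA, named after cytochrome f, was at 2647 ± 1710 CPM (n = 3) against 171.2 ± 75.7 (n = 2), and rpl33 at 1289 ± 641 against 125.9 ± 13.2. GLYMA_16G044100, listed beforehand under flowering time, was at 48.7 ± 42.7 CPM against 0.230 ± 0.326. The other tested member of that list, GLYMA_16G150700, was at 107.4 ± 74.8 against 2.96 ± 3.50 and did not pass (edgeR adjusted p = 0.122), and 2 of the 2 were higher when adjusted over the list alone.

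edgeR called 246 genes, 128 higher and 118 lower in trifoliate leaf. Across genes, which are not independent replicates, trifoliate libraries were not more alike than the leaf types. Replicate 1 correlated at 0.932 with true leaf replicate 2, and at 0.880 and 0.899 with trifoliate replicates 2 and 3. Trifoliate replicate 3 correlated at 0.903 and 0.908 with true leaf replicates 1 and 2, and at 0.829 with trifoliate replicate 2. The true leaf libraries correlated at 0.927 with each other. Of the 10 tested loci with plastid gene names, 5 were higher (9 when adjusted over the list alone), with a camera adjusted p = 6.63e-16 (adjusted p = 0.170 with an estimated correlation). petA changed by 3.95 ± 0.67 (edgeR adjusted p = 0.0267), rpl33 by 3.36 ± 0.45 (0.0179) and ndhC by 2.02 ± 0.41 (0.0495), and each was higher in all 3 trifoliate libraries than in both true leaf libraries. psbM, named after a photosystem II subunit, was at 173.7 ± 96.7 against 15.99 ± 4.83 CPM. rpl23-A and petG stood at 194.1 ± 119 against 36.5 ± 22 CPM and at 54.4 ± 44.9 against 7.40 ± 3.89 and did not pass (edgeR adjusted p = 0.0762 and 0.0839), and infA was lower in trifoliate replicates 2 and 3 (2.75 and 2.80 CPM) than in both true leaf libraries (4.24 and 3.13). GLYMA_16G044100 changed by 7.56 ± 1.39 (edgeR adjusted p = 0.0352). Among loci with no name in the files, GLYMA_20G208700 was higher at 508 ± 586 against 0.219 ± 0.211 CPM, and GLYMA_13G317600 lower at 2.38 ± 3.5 against 149.7 ± 112. The housekeeping gene TCTP was at 90.4 ± 43.2 against 22.7 ± 2.12 CPM. In trifoliate leaf, all 3 libraries carry barcodes of another list than the other 15 libraries, and 1 rRNA feature was among the calls, LSU_rRNA_eukarya (ENSRNA050000662) at 6771 ± 6150 against 123.3 ± 3.18 CPM. The count of calls was 2103 with DESeq2, 0 with only the 2 groups in the fit, 6 without true leaf replicate 1, 105 without true leaf replicate 2 and 1054 without trifoliate replicate 3. In simulated libraries of this comparison edgeR recovered 1.56% of genes changed by 2-fold and 35.4% by 4-fold (42542 genes). Without either true leaf library the calls of petA, rpl33, ndhC, psbM, TCTP, GLYMA_20G208700, GLYMA_16G044100 and LSU_rRNA_eukarya (ENSRNA050000662) ended (edgeR adjusted p up to 0.297), those of ndhC and GLYMA_16G044100 also without trifoliate replicate 1 (up to 0.163 and 0.256), and that of GLYMA_13G317600 without true leaf replicate 1 (0.184).

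Seed against the other organs asked which transcripts mark seed at every stage. Seed libraries carried most embryo maturation regulators, and the other 11 libraries held almost none of these transcripts. GLYMA_08G357600, listed beforehand under embryo maturation regulators, was at 99.2 ± 64.5 CPM (n = 7) in seed and 0.143 ± 0.288 (n = 11) elsewhere, and GLYMA_18G176100 ranged from 33.9 to 335.9 CPM in seed and averaged 0.204 ± 0.392 elsewhere. CHS7, a chalcone synthase, was at 235.5 ± 106 CPM in seed and 9.85 ± 18.7 elsewhere. CYP98A2, of phenylpropanoid metabolism, was lower in seed at 10.3 ± 5.35 against 75.6 ± 43.8 CPM.

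edgeR called 16833 genes, 9361 higher and 7472 lower in seed. Of the 7 embryo maturation regulators, 6 were higher (6 when adjusted over the list alone), with a camera adjusted p = 5.56e-05 (adjusted p = 0.463 with an estimated correlation). GLYMA_08G357600 changed by 10.70 ± 0.78 (edgeR adjusted p = 1.24e-06), and all 7 seed libraries lay above all 11 others. The remaining member, GLYMA_16G050500, was at 50.7 ± 15.1 against 64.5 ± 23 CPM (edgeR adjusted p = 0.143). Of the 8 storage and maturation genes named in the files, 4 were higher (5 when adjusted over the list alone), with a camera adjusted p = 0.0131 (adjusted p = 0.796 with an estimated correlation). SLE1 changed by 8.69 ± 0.38 (edgeR adjusted p = 9.7e-08), at 605.9 ± 1070 CPM in seed and 0.209 ± 0.306 elsewhere. GY1 and SLE2, near 0 in the younger seeds, did not pass (edgeR adjusted p = 1 and 0.0518). Of the 14 housekeeping genes named in the files, 5 were higher, with a camera adjusted p = 0.00394 (adjusted p = 0.723 with an estimated correlation). TCTP was at 634.9 ± 602 against 58.9 ± 32.9 CPM, and RPS13 (GLYMA_05G052300), a small-subunit ribosomal protein, at 87.2 ± 19.5 against 20.5 ± 9.5. Both tested loci listed beforehand under sugar transport were higher: GLYMA_08G183500 at 115.8 ± 61.9 against 7.02 ± 16.6 CPM and GLYMA_15G049200 at 12.9 ± 11.6 against 1.93 ± 5.12. Both overlapped with SAM replicate 2, at 55.5 and 17.1 CPM against lowest seed values of 34.8 and 0.210. Of the 9 tested seed globulins 5 were higher (5 when adjusted over the list alone; camera adjusted p = 0.299). The protease inhibitor locus and all 3 lipoxygenase loci listed beforehand were higher too, but in heart stage seed the latter overlapped with other organs: GLYMA_13G347600 was at 0.0162 to 0.276 CPM there and at 0.516 in green pod replicate 1. Both vegetative storage protein genes named in the files, VSPA and VSPB, were lower in seed. PPC16 was lower at 23.3 ± 8.34 against 66.8 ± 20.9 CPM (-1.55 ± 0.16, edgeR adjusted p = 7.57e-06).

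**Figure D3:**
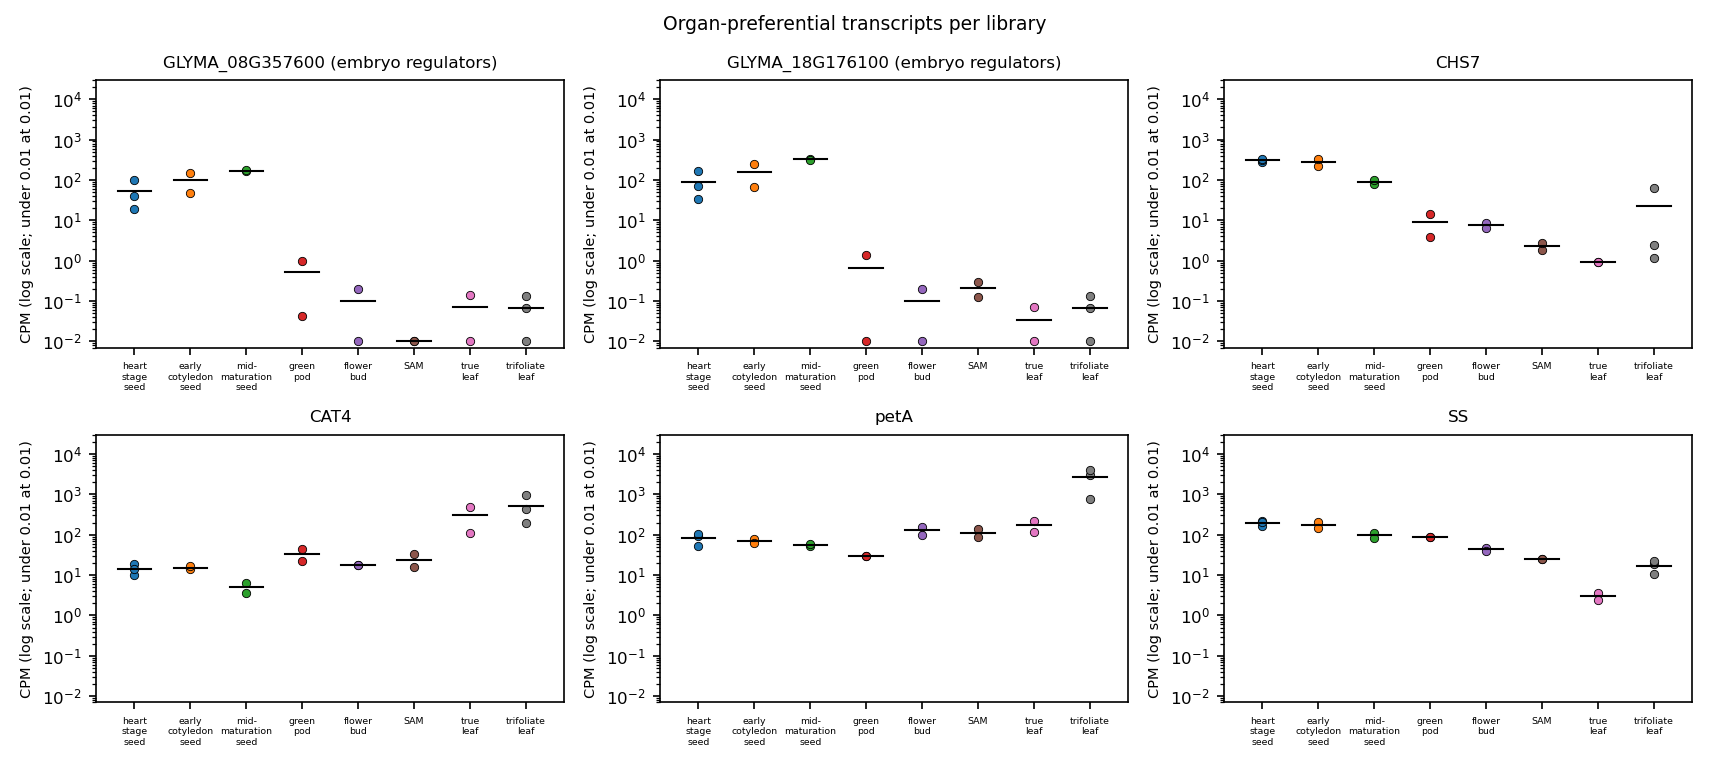
Levels of 6 genes in each library (y axis, CPM on a log scale, values under 0.01 drawn at 0.01) by group (x axis); dots are libraries and horizontal lines are group means. GLYMA_08G357600 and GLYMA_18G176100 lie higher in all 7 seed libraries than in the 11 others, CAT4 averages 436 CPM in leaf against 18.02 elsewhere, and SS averages 11.5 CPM in leaf against 111.8 elsewhere.

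Leaf against the other organs asked which transcripts mark leaf. CAT4, a catalase, was at 436 ± 327 CPM (n = 5) in leaf and 18.02 ± 10.9 (n = 13) elsewhere. The chloroplast elongation factor genes fusA1 and fusA2 were at 145.6 ± 152 and 92.4 ± 79.6 CPM in leaf against 12.03 ± 7.27 and 16.6 ± 6.3 elsewhere. SS, a sucrose synthase, was lower in leaf at 11.5 ± 8.73 against 111.8 ± 70.3 CPM.

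edgeR called 13029 genes, 7197 higher and 5832 lower in leaf. Of the 10 tested loci with plastid gene names, 9 were higher (9 when adjusted over the list alone), with a camera adjusted p = 2.68e-10 (adjusted p = 0.256 with an estimated correlation). They include petA at 1657 ± 1820 against 79.7 ± 38.4 CPM and ndhC at 122.3 ± 81.7 against 19.8 ± 9.09. The trifoliate libraries, of the other barcode list, stood highest: true leaf replicate 2 held petA at 117.7 and ndhC at 26.5 CPM, below flower bud replicate 2 (156.5 and 39.6). infA changed by 0.84 (edgeR adjusted p = 0.0438), under the fold asked for. CAT4 changed by 4.35 ± 0.42 (edgeR adjusted p = 1.35e-05) and SS by -3.12 ± 0.22 (2.56e-06), and for both, all 5 leaf libraries lay on 1 side of all 13 others. FTRC, a ferredoxin-thioredoxin reductase, was at 72.3 ± 45.3 against 12.1 ± 5.01 CPM. GLYMA_15G127500, with no name in the files, was at 132.4 ± 97.6 against 0.0902 ± 0.139 CPM, and GLYMA_19G034500 at 0.0541 ± 0.056 against 242.7 ± 192, from 3 UMIs in leaf (ratio of the other organs to leaf 6050, counting interval 2070 to 29337). GLYMA_10G221500, listed beforehand under circadian clock, was at 735.1 ± 287 against 270.1 ± 229 CPM (1.30 ± 0.22, edgeR adjusted p = 0.000584). GLYMA_16G150700, listed beforehand under flowering time, was at 65.6 ± 77.9 against 10.8 ± 27.2 CPM, and its call ended without true leaf replicate 2 (edgeR adjusted p = 0.161). GLYMA_10G221500 and GLYMA_16G150700 were about as high in green pod as in leaf. The 5 catalase and superoxide dismutase genes named in the files had no camera call in any comparison (lowest adjusted p = 0.223).

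Green pod against the other organs asked which transcripts mark the young pod. GLYMA_16G019400, listed beforehand under pod dehiscence, was at 61.3 ± 16.9 CPM (n = 2) in pod and 4.24 ± 4.92 (n = 16) elsewhere. LOX1.4, a lipoxygenase, was at 379.5 ± 125 against 111.5 ± 79 CPM. Of the 10 tested loci with plastid gene names, 6 were lower in pod (camera adjusted p = 8.68e-05; adjusted p = 0.584 with an estimated correlation), among them rpl33 at 21.8 ± 3.72 against 293.8 ± 547 CPM and petA at 29.8 ± 0.771 against 578.7 ± 1200.

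edgeR called 7999 genes, 4068 higher and 3931 lower in pod. GLYMA_16G019400 changed by 4.36 ± 0.85 (edgeR adjusted p = 0.00455), and both pod libraries lay above each of the other 16. GLYMA_16G150700, listed beforehand under flowering time, changed by 5.62 ± 0.79 (edgeR adjusted p = 0.000698), at 67.1 ± 36.6 against 20.9 ± 50.9 CPM. GLYMA_10G221500, listed beforehand under circadian clock, was at 698.6 ± 385 against 361.9 ± 304 CPM (1.36 ± 0.28, edgeR adjusted p = 0.00629). Neither was particular to pod: mean levels were higher in trifoliate leaf for GLYMA_16G150700 and in leaf for GLYMA_10G221500. Of the 10 loci with plastid gene names, 8 were lower when adjusted over the list alone. petG and infA did not pass (edgeR adjusted p = 0.16 and 0.0589), and psbN was at 0.602 and 1.84 CPM in pod against 0.241 and 0.507 in flower bud. GLYMA_07G236900, with no name in the files, was at 61.0 ± 20.1 against 2.05 ± 6.75 CPM. GLYMA_18G087300 had 0 UMIs in pod and was at least 142-fold lower against a floor of 3 counts over the group. Both soyasaponin genes named in the files were lower. The 13 flavonoid and isoflavonoid enzyme genes had no camera call in any comparison (lowest adjusted p = 0.229), nor had the 7 glycerolipid synthesis genes (lowest 0.154), of which 2 were higher in pod and which fry called higher there (adjusted p = 0.00655). The count of calls was 1814 without pod replicate 1 and 4587 without pod replicate 2. The calls of LOX1.4 (edgeR adjusted p up to 0.282) and petA (0.126) ended without either pod library, that of LOX1.4 also without flower bud replicate 1, and those of rpl33 (0.073) and GLYMA_10G221500 (0.309) without pod replicate 1.

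Flower bud against the other organs asked which transcripts mark the developing flower. GLYMA_16G091300, listed beforehand under floral organ identity, was at 131.7 and 156.4 CPM in flower bud (n = 2) and averaged 7.60 ± 29.4 (n = 16) elsewhere. GLYMA_06G163600, of the same list, was at 6.26 and 2.33 CPM in flower bud against 1.17 ± 2.13 elsewhere, where SAM replicate 2 was higher still (8.60), and GLYMA_16G091300 was at 117.7 CPM in that library. GLYMA_19G061600, with no name in the files, was at 148.6 ± 16.5 against 0.0450 ± 0.0784 CPM.

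edgeR called 2879 genes, 2648 higher and 231 lower in flower bud. Of the 3 floral organ identity loci, 2 were higher (3 when adjusted over the list alone). GLYMA_16G091300 changed by 8.47 ± 1.09 (edgeR adjusted p = 0.00113) and GLYMA_06G163600 by 5.05 ± 0.81 (0.00498), each higher in both flower bud libraries than in the mean of the others. GLYMA_19G061600 changed by 12.79 ± 0.44 (edgeR adjusted p = 3.59e-07), and GLYMA_05G006100 had 928 UMIs in flower bud and 1 elsewhere (ratio 20038, counting interval 3588 to 792319). GLYMA_04G202000, the other floral organ identity locus, was at 0.452 ± 0.496 against 0.148 ± 0.385 CPM and did not pass (edgeR adjusted p = 0.187). rRNA features were among the higher calls, such as LSU_rRNA_eukarya (ENSRNA050000638) at 306.3 ± 206 against 29.3 ± 37.7 CPM. GLYMA_02G216700 was lower at 4.38 ± 0.164 against 23 ± 15.2 CPM. VSPA and VSPB, vegetative storage proteins, averaged 532 ± 47.2 and 284 ± 11.5 CPM in flower bud. Neither was called by edgeR over all genes. Both were higher when adjusted over their list alone, which holds only these genes and was made after the data had been seen. SAM replicate 1 stood higher than flower bud for both. The count of calls was 979 without flower bud replicate 1, 786 without flower bud replicate 2, 4378 without the 3 trifoliate libraries, and 2840 without SAM replicate 2, which correlated better with flower bud than with SAM replicate 1. The call of GLYMA_06G163600 ended without flower bud replicate 1 (edgeR adjusted p = 0.0779), and that of LSU_rRNA_eukarya (ENSRNA050000638) without flower bud replicate 2 (0.195).

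SAM against the other organs asked which transcripts mark the shoot apex. GLYMA_08G356900 and GLYMA_20G172600, with no name in the files, were at 45.1 ± 3.12 and 53.7 ± 1.48 CPM (n = 2) in SAM against 1.70 ± 4.35 and 4.69 ± 12.7 (n = 16) elsewhere. The SAM libraries differed from each other at floral loci: GLYMA_16G091300, listed beforehand under floral organ identity, was at 0.310 CPM in replicate 1 and 117.7 in replicate 2, against a mean of 144 in flower bud. VSPA and VSPB were at 1426 and 1262 CPM in SAM replicate 1 and at 57.2 and 16.2 in replicate 2.

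edgeR called 2749 genes, 2467 higher and 282 lower in SAM. GLYMA_08G356900 changed by 8.27 ± 0.89 (edgeR adjusted p = 0.000387) and GLYMA_20G172600 by 7.17 ± 0.50 (2.16e-05). GLYMA_04G238200 was lower at 0.715 ± 0.0472 against 39.3 ± 70.7 CPM, and GLYMA_10G217900 at 2.26 ± 1.88 against 33.3 ± 28.2. Of the 3 floral organ identity loci, 2 were called higher (3 when adjusted over the list alone), with GLYMA_16G091300 at 6.86 ± 1.07 (edgeR adjusted p = 0.00375). Without SAM replicate 2 the change of GLYMA_16G091300 was -0.69, and the call of GLYMA_06G163600 ended (edgeR adjusted p = 0.199). Across genes, which are not independent replicates, SAM replicate 2 correlated at 0.948 and 0.944 with flower bud replicates 1 and 2 and at 0.927 with SAM replicate 1. The count of calls was 1220 without SAM replicate 1 and 874 without SAM replicate 2. It was 1439 and 1484 without flower bud replicates 1 and 2, 1603 without green pod replicate 1 and 4133 without trifoliate replicate 3. The calls of GLYMA_04G238200 (edgeR adjusted p up to 0.147) and GLYMA_10G217900 (0.141) ended without SAM replicate 1, the former also without SAM replicate 2.

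**Figure D4:**
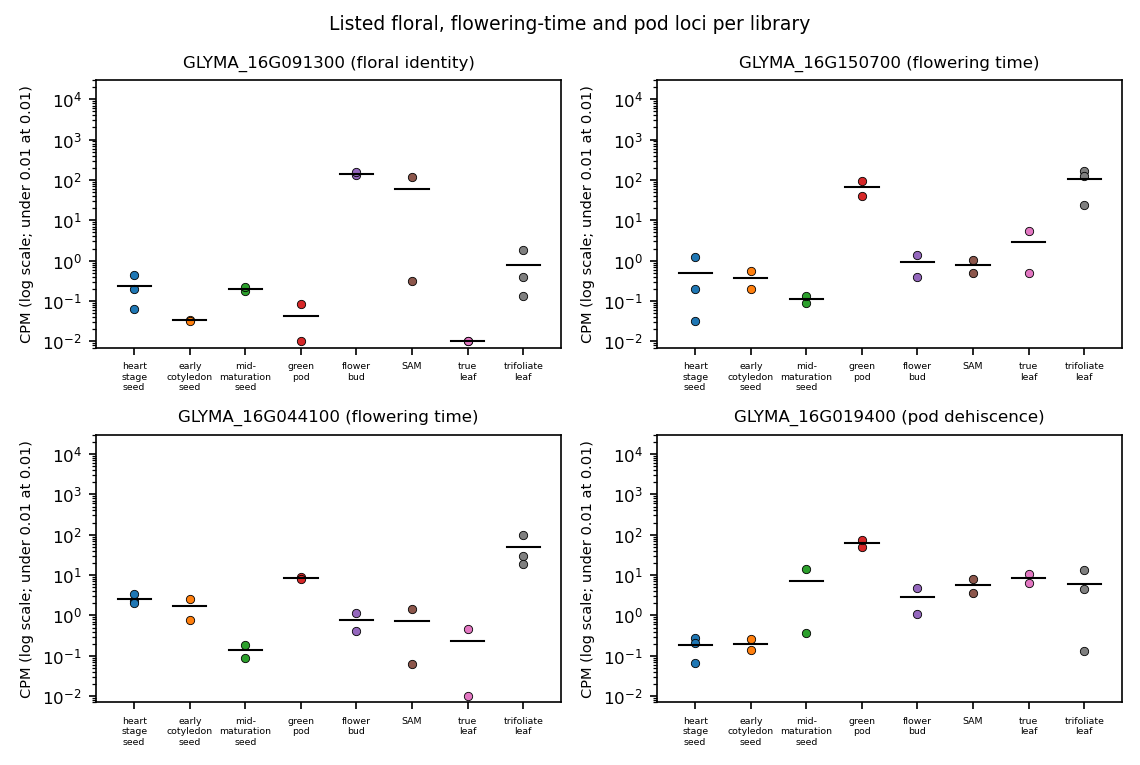
Levels of 4 loci listed beforehand in each library (y axis, CPM on a log scale, values under 0.01 drawn at 0.01) by group (x axis); dots are libraries and horizontal lines are group means. GLYMA_16G091300 is at 0.310 CPM in SAM replicate 1 and 117.7 in replicate 2, GLYMA_16G150700 and GLYMA_16G044100 average 107.4 and 48.7 CPM in trifoliate leaf, and GLYMA_16G019400 averages 61.3 CPM in green pod.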

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

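Of the tests below, the one on library depth, the ones on flower bud transcripts in SAM replicate 2 (the median ratio, the count of missing transcripts and the wider set of 49), the fit within embryo-like nuclei and the removals of shared barcodes and of rRNA and plastid-named features were chosen only after the results they bear on were seen.

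Up to 452 nuclear barcodes were the same in a pair of heart or early cotyledon seed libraries, a signal in the barcode lists that no comparison above uses. The 10 pairs of these 5 libraries shared 179 to 452 barcodes (median 344), while 85 other pairs of libraries outside trifoliate leaf shared 0 to 22 and the 3 pairs of trifoliate libraries 49 to 150. These 5 libraries shared 35 to 92 barcodes with green pod replicate 2 and 39 to 46 with SAM replicate 2. Shared barcodes held 15.4% to 23.2% of the UMIs in the heart and early cotyledon libraries, on whichever side of a pair: in 28.02% to 64.02% of the barcodes shared by a pair, the larger side held at least 10 times the UMIs of the smaller (medians of 68290 to 96093 against 630 to 698). In those, the smaller side's profile had a median cosine of 0.322 to 0.358 with the larger side under the same barcode, against 0.282 to 0.303 with other barcodes.

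No gene was called by edgeR between heart stage and early cotyledon seed, where 6 were called by DESeq2, and across genes the early cotyledon libraries correlated better with heart stage libraries of the same number (0.972 and 0.955) than with each other (0.931). The gap between the mean of the former and the latter was 0.0325 (bootstrap interval 0.0304 to 0.0345) with all nuclei and 0.0311 without shared barcodes, which argues against these barcodes as its cause, and without them 0 genes were called by edgeR, with 471 at an unadjusted p under 0.05. Without embryo-like nuclei the gap was 0.0222 (0.0204 to 0.0244), so unequal shares of such nuclei are not its whole cause, though the gap shrank; within them it was 0.0145, and early cotyledon replicate 1 correlated at 0.918 with heart stage replicate 1 and at 0.928 with early cotyledon replicate 2, against the pattern, with 0 genes called by edgeR (673 at an unadjusted p under 0.05). The gap covers same-numbered pairs only and leaves out heart stage replicate 3. By log2 CPM without TMM scaling, early cotyledon replicates 1 and 2 correlated at 0.965. With heart stage replicates 1 to 3, replicate 1 correlated at 0.985, 0.967 and 0.979, and replicate 2 at 0.945, 0.980 and 0.960. Early cotyledon replicate 1 was thus nearer to every heart stage library, not only to the one of its number. Unequal shares of the other, unnamed groups of nuclei, a shared preparation of same-numbered samples, and a true likeness of the stages stay open and were not tested.

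Between trifoliate and true leaf, edgeR called 246 genes (0 with only the 2 groups in the fit, 2103 by DESeq2) in a comparison where all 3 trifoliate libraries carry barcodes of another list. Of the calls on other genes, 93.75% remained without rRNA features and loci with plastid gene names. In trifoliate libraries the former held 0.177% to 1.30% of UMIs and the latter 0.150% to 0.617%. Their removal could therefore change little and does not decide whether dominant features play a part. GLYMA_09G164000, with 4.77%, 9.94% and 9.60% of UMIs in trifoliate replicates 1 to 3, was not removed. With every library thinned to the smallest, 67.48% of all calls remained, which argues against depth as the whole cause. In 39.84% of the called genes, each trifoliate library lay outside the range of all 15 others. Library chemistry and leaf type cannot be told apart here, since every trifoliate library and no true leaf library has that list. A difference between the leaf types stays open, as untested.

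SAM replicate 2 held transcripts that flower bud libraries hold and SAM replicate 1 lacks: over 15 transcripts of flower bud alone its median level was 1.03 times that of flower bud, but 12 of them are among the transcripts that make up the pattern, so this value restates it. The other 3 (GLYMA_19G061600, GLYMA_05G006100 and GLYMA_16G073000) stayed under 10% of that ratio. VSPA and VSPB lay far below flower bud (57.2 against 498.6 and 565.4 CPM, and 16.2 against 275.6 and 291.9). Neither result is what material like that of the flower bud libraries would give alone. GLYMA_08G356900 was at 47.3 CPM in replicate 2 and 42.9 in replicate 1 against 13.9 and 11.7 in flower bud. It was picked because both SAM libraries lay above all others, so its level in replicate 2 decides nothing here. Over the 3 transcripts of SAM replicate 1 that flower bud lacks, the median ratio of replicate 2 to replicate 1 was 0.000514. Over 49 transcripts at least 5 times higher in replicate 1 than in flower bud, replicate 2 lay at a median place of 0.0115 between flower bud (0) and replicate 1 (1), with an interval of -0.0195 to 0.0433. Picking transcripts high in replicate 1 and low in flower bud pulls both values toward 0. They are what a flower bud library under the label of SAM replicate 2 would give, but with this selection they do not decide it. Flower bud material mixed into SAM replicate 2, and a later, reproductive apex, which would carry flower transcripts too, stay open as well. The labels give no age for SAM, and a reproductive apex was not tested.

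For seed minus other organs, 1 of 60 splits drawn from the libraries gave as many calls, the real one with 16833, and the highest other gave 22. For leaf minus other organs, 1 of 60 splits gave as many, the real one with 13029, and the highest other gave 18. The other splits put libraries of different organs into the same group, which widens the spread within groups and leaves few calls in any comparison. They show that the labelled groups are more alike within than mixed ones. They cannot tell how many of the seed or leaf calls arose by chance.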

How the results depend on the processing

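Among the alternatives below, removal of nuclei by Scrublet score, the 2-group fit with a block, the fits without rRNA and plastid-named features, without trifoliate libraries and without shared barcodes were chosen only after the data had been seen. With DESeq2's size factors in edgeR, no low-count filter, either removal of doublets, or thinning, the count of calls stayed within 1.5 times of the main one in all 8 comparisons, as it did for the fits without shared barcodes (6401 in mid-maturation minus early cotyledon seed) and without rRNA and plastid-named features (225 in trifoliate minus true leaf). All 132 calls of named genes kept their direction and threshold with DESeq2's size factors. DESeq2 called 6 genes (5 higher, 1 lower) in early cotyledon minus heart stage seed against 0 by edgeR, where 586 by DESeq2 had an unadjusted p under 0.05. It called 9740 against 6484 in mid-maturation minus early cotyledon seed and 2103 against 246 in trifoliate minus true leaf. Its share of higher calls was 67.9% against 52.0% in trifoliate minus true leaf, 39.5% against 50.9% in green pod and 76.8% against 89.7% in SAM minus other organs. Replicate numbers did not pair the samples over all groups: of 57 same-numbered pairs, 6 had deviations that correlated above 0.1 (median -0.00912 across genes). Among these 6 were heart stage and early cotyledon replicates 1 (0.589) and 2 (0.608). In a group of 2 libraries the deviations are mirror images, so these pairs are not independent. Both of the last values rest on 1 contrast between the early cotyledon libraries. With a replicate block, edgeR called 70 genes in trifoliate minus true leaf, and in the other comparisons 0, 5717, 16557, 12740, 7138, 2686 and 2513, in the order of the report. With only the 2 groups in the fit, edgeR called 3029 genes in mid-maturation minus early cotyledon seed and 0 in trifoliate minus true leaf. With a replicate block as well, these counts were 862 and 0. Such a fit has fewer libraries to estimate the spread, but takes no spread from other groups. By log2 CPM, trifoliate libraries correlated at 0.829 to 0.899 with each other and heart stage libraries at 0.959 to 0.987. Whether fewer libraries or a wider spread in leaf gave the 0 calls was not tested. Flower bud minus other organs had 4378 calls without the 3 trifoliate libraries against 2879. Of 12 list calls by camera, 0 remained with an estimated correlation, and fry called 11 of the lists and comparisons tested, 3 of them glycerolipid synthesis (mid-maturation minus early cotyledon seed, green pod and flower bud; adjusted p = 0.00182, 0.00655 and 0.036), and none in early cotyledon minus heart stage seed. Leaving out 1 library at a time gave 0 to 0 calls in early cotyledon minus heart stage seed, 1555 to 5215 in mid-maturation minus early cotyledon seed, 6 to 1054 in trifoliate minus true leaf, 15381 to 17308 in seed, 9653 to 13980 in leaf, 1814 to 9942 in green pod, 786 to 4096 in flower bud and 874 to 4133 in SAM minus other organs; a lone library was assumed to vary like the other groups. Of the 132 named calls, 80 held whichever library was left out and 52 ended in some refit. GLYMA_16G091300 in SAM minus other organs reversed, to -0.69 without SAM replicate 2, and was 7.86 without SAM replicate 1. The mean share of storage cotyledon-like nuclei in mid-maturation seed was 7.695% at Leiden resolution 0.4 and 8.136% at a minimum of 1000 UMIs, against 26.6%, a fall that came from replicate 2. Where no cause is given, the cause was not tested. Not run, with all their alternatives, were the planned tests within endosperm-like, seed coat-like, embryo-like (mid-maturation minus early cotyledon seed) and mesophyll-like nuclei. Depth limits the smallest libraries most: 1 UMI in trifoliate replicate 3 stands for more CPM than in any other.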

Other observations

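All clusters in this part were made after the data had been seen, without the loci listed beforehand, and no hypothesis was tested on them.

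In leaf, transcripts of both flowering time loci were concentrated in few nuclei. A group of 1107 leaf nuclei, 3.27% of the total, held 83.7% of the UMIs of GLYMA_16G150700 and 84.5% of those of GLYMA_16G044100, or 71.8% and 72.9% without trifoliate replicate 1. The lowest share in a library was 23.3% for GLYMA_16G150700 (true leaf replicate 2) and 49.6% for GLYMA_16G044100 (trifoliate replicate 3). At least 1 UMI of GLYMA_16G150700 was found in 31.5% of these nuclei and in 1.33% of the others, at median depths of 1813 and 1469 UMIs. For GLYMA_16G044100 the shares were 30.4% and 0.645%. Another leaf group, of 3220 nuclei, held 87.3% of the UMIs of CHS7 and 73.4% of those of IFS2, an isoflavone synthase, but 3090 of these nuclei came from trifoliate replicate 2, 79.5% of that library. Without that library the group held 18 of 59 UMIs of CHS7 (30.5%) and 12 of 61 of IFS2 (19.7%), so the shares follow 1 library.

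In seed, the sugar transport loci listed beforehand were most concentrated in a group of 1038 nuclei (2.28%), which held 51.4% and 26.6% of their UMIs. The shares for GLYMA_15G049200 and GLYMA_08G183500 were 67.2% and 40.7% in heart stage replicate 2, 7.69% (1 of 13 UMIs) and 8.62% in heart stage replicate 1, and 0 in both mid-maturation libraries, which had no nuclei in the group. A group with 3.26% of seed nuclei held 53.4% of the UMIs of VSPA, of which 1477 of 1807 came from heart stage replicate 1, and 30.5% without that library. A group of 149 nuclei, of which 142 came from mid-maturation replicate 2, held 68.6% of the seed UMIs of GLYMA_16G019400, the pod dehiscence locus, and 0 of 63 without that library. Of the genes named in the files, HSP17.3-B, 1 of 3 tested small heat shock protein genes, was higher in mid-maturation than in early cotyledon seed, GMN16 was lower there, and CHLI, 1 of 2 chlorophyll synthesis genes, was higher in leaf than in the other organs.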
